A study of Mus musculus with 9 samples.

How the data were processed

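The samples were 9 single-channel Affymetrix 3' arrays of mouse CD4+CD25+ Treg cells on a C57Bl/6 background, 3 from CBP-deleted, 3 from p300-deleted and 3 from control mice. Per the labels, total RNA was isolated with RNeasy, 100 ng was amplified and labelled with biotin, and the replicates are independent samples. The deposited values are 1 per probe set and array on a log2 scale. According to the processing notes the authors summarised the probe sets with RMA, for which no version, background or annotation settings are stated. The array medians of 5.49 to 5.59 lie in the range of log2 RMA values. They were used as deposited, with no further transformation or filter.

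The table has 22690 probe sets. After 64 control probe sets were set aside, 22626 remained. Of these 20380 carry a single gene symbol in the annotation used, 691 carry several and 1555 are not named here. Genes were matched to the NCBI RefSeq annotation of GRCm38.p6, which was used for gene names and for the order of neighbouring genes; 29 gene identifiers had no match and 0 symbols were changed. Where a gene had several probe sets, the one with the highest mean over all 9 arrays was used, a choice made without the groups. This gave 12393 genes. Probe sets with several symbols or no name were tested on their own only as an alternative. For arrays no depth per sample exists, and the number of arrays limits the precision.

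Each comparison (CBP-deleted against control, p300-deleted against control, CBP-deleted against p300-deleted) was tested with limma 3.58.1 in R 4.3.3: 1 mean per group over all 9 arrays, 6 residual degrees of freedom, empirical Bayes moderation with a trend on mean expression, and Benjamini-Hochberg adjustment over all genes at 0.05. No covariate was used. All tests are two-sided. An exact permutation test of 3 arrays against 3 cannot give a p below 0.1, so none was used for single genes. Standard errors of single genes are those of the limma fit, and standard deviations are over the 3 arrays of a group. Standard errors of a median over genes, or of a difference of such medians, come from the spread across genes. They treat genes as independent and do not measure the spread between arrays. Il2ra, Foxp3 and Crebbp were also tested for every probe set.

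Before the data were examined, 36 gene lists were fixed, 25 of pathways and cell states and 11 of cell type markers. The sex-linked list served only to describe the arrays, and the other 35 were tested with camera (limma) at its preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 35 lists of a comparison; each tested list had at least 3 measured genes. Camera with a correlation estimated for each list, and fry, a rotation test of whether the genes of a list move on balance one way, were run as alternatives. With the estimated correlation 0 lists passed in any comparison, and with fry 4, 2 and 8 passed. Members are counted by the adjustment over all genes and by an adjustment over the list alone.

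Also fixed beforehand were the named genes. They are, for each comparison, the CBP and p300 genes and Foxp3, the 12 genes with the highest and the 12 with the lowest log2 fold change among those past the threshold whose arrays do not overlap between the groups (predicted and unnamed genes left out), and for each list up to 4 members past the threshold with the largest change, or else up to 2 given as values. Genes named outside this rule were chosen after their values were seen. In the report these include Gpr83, Izumo1r and Ctla4 against the control, Sdc1, and the genes that changed in both knockouts or in opposite directions. They also include genes near Apobec3 and Foxp3, and genes linked to mast cells and basophils. One kappa variable segment that met the rule in 2 comparisons is not reported here.

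The count of genes changed in both knockouts was set beside 100 simulations of unchanged groups that share 3 simulated controls, and beside the overlap of independent lists. The procedure was tested on simulated data: 10 sets per comparison were drawn from the control means and the moderated variances of the 12393 genes, with 200 genes and the cell cycle list changed. At a log2 change of 0.5, 1 and 2 the share recovered was 50.6%, 98.3% and 100% for CBP-deleted against control, 48.6%, 98.1% and 99.7% for p300-deleted against control, and 50.7%, 97.9% and 99.8% between the knockouts. The share of false calls was 5.92%, 6.07% and 4.98%. The cell cycle list, shifted by 0.5, was called in 10 of 10 sets in each comparison, and 0.294%, 1.18% and 0% of the other lists were called. Genes were simulated independently of each other, whereas the estimated correlation of the cell cycle list in the data was 0.78. The list rates therefore do not carry over to the data, where other splits of the arrays called up to 11, 12 and 13 lists.

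The alternatives fixed beforehand were: leaving out dim probe sets, the mean of all probe sets of a gene, every probe set on its own, leaving out probe sets with shared probes, extra quantile normalization, subtraction of each array's median, only the arrays of the 2 groups compared, moderation without a trend, array weights, the replicate number as a block, leaving out each array in turn, a 1.5-fold threshold, an adjusted p of 0.1, and the other list tests. Added after the values were seen were the 18S level as a covariate, leaving out CBP-deleted replicate 3 and p300-deleted replicate 1 together (the arrays highest in neutrophil transcripts), and the correlation without Foxp3. Together with the single arrays left out this makes 26 settings. Tables were handled with data.table (version 1.17.8), and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.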

Results

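Transcripts were measured in regulatory T (Treg) cells, the CD4+ T cells that depend on the transcription factor Foxp3 and restrain immune responses. The cells came from mice in which CBP or p300, related acetyltransferases of histones and other proteins, had been deleted by a Cre recombinase driven from Foxp3. The question addressed is whether Treg cells need each enzyme to develop and function. CD4+CD25+ cells were separated with magnets, and 3 arrays were run for each of 3 groups: CBP-deleted, p300-deleted and control. The genotype labels and the design text give the control mice as Foxp3cre, and the design text and sample names also call them wild type. If they carry no Foxp3cre allele, a difference from them cannot be assigned to the deletion alone. Each array held 22690 probe sets of an Affymetrix 3' design, of which 64 were control probe sets. The gene comparisons used 12393 genes, each read by 1 probe set. The values are on a log2 scale, and the array medians lay between 5.49 and 5.59. The precision is limited by the number of arrays, 3 per group.

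Arrays of one group correlated at 0.994 to 0.997 for CBP-deleted cells, 0.994 to 0.996 for p300-deleted cells and 0.988 to 0.993 for controls. Between groups the correlations were 0.985 to 0.994. The first principal component held 27.2% of the variance and placed all 3 controls above all 6 knockout arrays. The second held 24.7% and placed the CBP-deleted arrays above the others. All 9 arrays carried transcripts of the Y-linked gene Eif2s3y (log2 8.18 to 9.30) and had Xist, which female cells express, at log2 3.44 to 3.80. Probe sets for 18S ribosomal RNA, which are not part of the gene comparisons, averaged log2 6.97 ± 1.66 (SD, n = 3) in controls, 7.75 ± 0.32 in CBP-deleted and 8.52 ± 0.96 in p300-deleted arrays. Among the controls, replicates 1 and 2 read 5.82 and 6.20 and replicate 3 read 8.88.

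The genes that define the experiment were examined first. The Foxp3 reading fell from log2 9.60 ± 0.14 (SD, n = 3) in controls to 2.87 ± 0.12 in CBP-deleted and 2.95 ± 0.32 in p300-deleted cells. These were log2 fold changes of -6.73 and -6.65 (SE 0.16 each), with limma adjusted p of 4.07e-10 and 4.66e-10. The knockout readings lie below those of Xist in the same male cells (3.44 to 3.80), a level not told from background. Both values are therefore lower bounds for the fall in what this probe set reads. Only 9.10% to 21.3% of the probe sets lay below Foxp3 in the 6 knockout arrays, against 91.4% to 92.8% in the controls. The Foxp3 levels of the 2 knockouts differed by -0.08 (SE 0.16, adjusted p = 0.859). Foxp3 was read by 1 probe set, and the labels do not say which part of the transcript it reads. A probe set that does not read the transcript of the Cre-bearing Foxp3 allele could give these readings. A fall of the transcript itself is therefore not established. Crebbp, the gene of CBP, was read by 1 probe set, at 7.53 ± 0.16 in controls, 7.20 ± 0.13 in CBP-deleted and 7.56 ± 0.10 in p300-deleted cells. Its difference of -0.33 (SE 0.11) between CBP-deleted and control cells did not pass (adjusted p = 0.123), nor did the -0.36 between the knockouts (adjusted p = 0.101). In p300-deleted cells Crebbp differed from the control by 0.03 (adjusted p = 0.930). The deleted exon is not given in the labels, so a probe set outside it cannot check the deletion. The gene of p300 is not analysed here. Il2ra, which encodes the CD25 used for the separation, had 2 probe sets, and neither changed in either knockout. The brighter one read 9.05 ± 0.25 in controls, 9.09 ± 0.14 in CBP-deleted and 9.29 ± 0.06 in p300-deleted cells. The Crebbp call depended on the setting: without control replicate 3 the difference between CBP-deleted and control cells was -0.42 with an adjusted p of 0.0399, in a range of 0.0328 to 0.371 over 21 alternatives.

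Other genes of the Treg signature went both ways. In CBP-deleted cells Il10, the gene of an inhibitory cytokine, rose 1.97-fold (log2 0.98, SE 0.16), and Plagl1, a zinc finger factor, rose 2.34-fold. The rise of Plagl1 rests on 1 of its 2 probe sets: with probe sets ending in _x_at left out it was 0.35 (adjusted p = 0.456, range over 21 alternatives 0.00195 to 0.456). Ecm1, an extracellular matrix protein, fell by 1.38 and Gpr83, an orphan receptor, fell by 0.54 on the log2 scale. In p300-deleted cells Il10 rose 1.87-fold, Izumo1r, a folate receptor family member, rose by 0.60, and Rgs1, a regulator of G protein signalling, rose by 0.61, while Klrg1, a receptor of effector cells, fell by 1.14. Ctla4, an inhibitory receptor, rose by 0.56 in CBP-deleted cells (adjusted p = 0.0165) and was 0.32 higher in p300-deleted cells (adjusted p = 0.124). Of the 30 measured members, 5 rose and 6 fell in CBP-deleted cells (5 and 12 adjusted over the list alone), and 4 rose and 2 fell in p300-deleted cells (7 and 5 adjusted over the list alone). The list as a whole was not shifted against the control in CBP-deleted (median -0.21, adjusted p = 0.133) or p300-deleted cells (median 0.18, adjusted p = 0.248). In CBP-deleted cells it was shifted down with fry (adjusted p = 0.00880) and with the 18S level as a covariate (0.0371, in a range over 23 alternatives of 0.00880 to 0.757). Foxp3 itself is in the list and enters these calls, so they do not show that the other members fell. In p300-deleted cells the mean of the list was -0.15, of the other sign, because the low Foxp3 reading enters it. The plot of Treg genes by array shows Foxp3 beside these members.

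**Figure D1:**
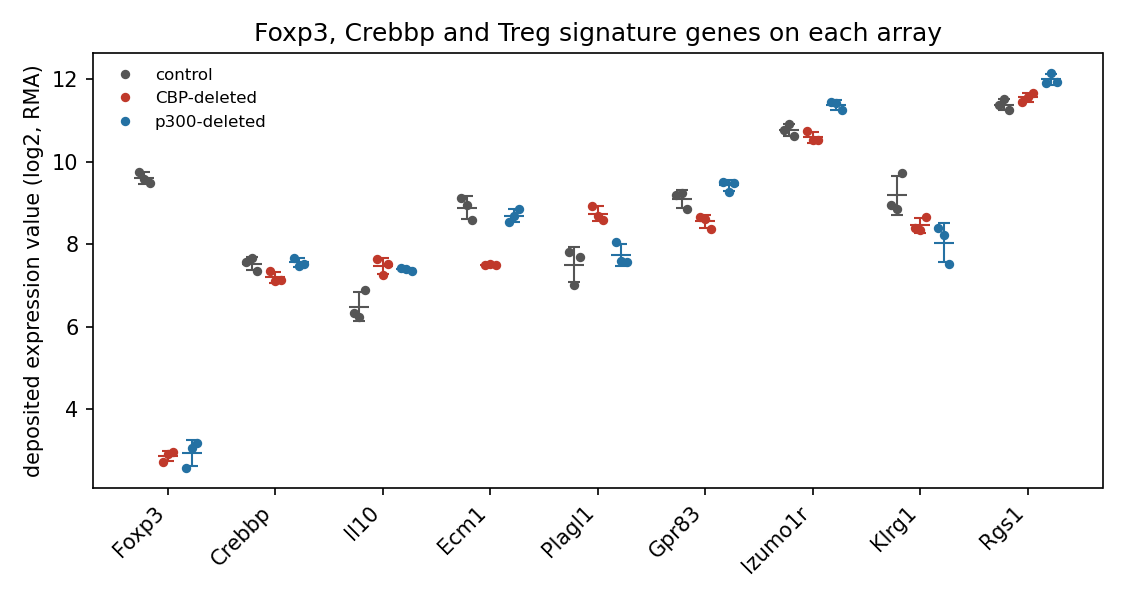
Log2 expression (vertical axis) of Foxp3, Crebbp and 7 further named genes in each of the 9 arrays, by group on the horizontal axis; points are arrays, bars the group means and error bars the SD (n = 3). Foxp3 lies between 2.58 and 3.19 in the 6 knockout arrays and between 9.48 and 9.75 in the controls, while Il10 is higher in both knockouts.

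CBP-deleted and control cells were compared to find which transcripts depend on CBP in Treg cells. Leaving the Foxp3 reading aside, the genes that fell furthest were Cnr2, the cannabinoid receptor of immune cells (2.96-fold, log2 -1.57, SE 0.20), and Mmp9, a matrix-degrading protease (2.73-fold, log2 -1.45, SE 0.30). Sostdc1, a secreted antagonist of BMP and Wnt signals, rose from log2 3.57 ± 0.41, at the level of Xist in these male cells, to 5.57 ± 0.32 (SD, n = 3), so its log2 fold change of 2.01 is a lower bound. Penk, the precursor of enkephalin peptides, rose 3.51-fold from 8.39 ± 0.14 to 10.21 ± 0.20 (log2 1.81, SE 0.14, adjusted p = 0.000143). Il21, a T cell cytokine, rose 2.45-fold, and Igfbp4, a binding protein of insulin-like growth factors, rose 2.54-fold, with all 6 of its probe sets higher. In all, 611 of 12393 genes changed, 265 higher and 346 lower; 105 of those higher and 149 of those lower changed at least 1.5-fold. In each of the 611 the 3 CBP-deleted arrays lay on one side of the 3 controls. Over all genes 24.4% separated in this way, where chance gives 10%.

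The other leading genes that rose in CBP-deleted cells were Klrb1b, an NK cell receptor (1.76, with 1 of the 3 controls, replicate 2, below the level of Xist at 2.77), Stfa3, a cysteine protease inhibitor (1.53), Cpq, a carboxypeptidase (1.49), and Gucy1b1, a subunit of soluble guanylate cyclase (1.40), as log2 fold changes. They were followed by Oasl2, an interferon-induced gene (1.27), Plagl1 (1.22), Tmem242 (1.21) and Ahr, the aryl hydrocarbon receptor (1.21). For Cpq and Ahr the second of their 2 probe sets had the opposite sign. Those that fell were Gbp2b, a guanylate-binding protein (-1.43), Plxnd1, a semaphorin receptor (-1.42), Ckb, the brain-type creatine kinase (-1.38), and the cell surface proteoglycans Sdc4 (-1.35) and Gpc1 (-1.30). Pde2a, a cyclic nucleotide phosphodiesterase (-1.30), Aqp9, a water and glycerol channel (-1.27), and Klra17, a member of the Ly49 receptor family (-1.25), also fell. The changes of Gucy1b1 and Klra17 are lower bounds too, since their lower groups read 3.62 and 3.15.

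Of 16 measured NF-kappaB targets, 8 fell in CBP-deleted cells and 0 rose (10 and 0 adjusted over the list alone), with a median log2 fold change of -0.34. Tnf, an inflammatory cytokine, fell by 0.74 (SE 0.12), Traf1, an adaptor of TNF receptors, by 0.64, Icam1, an adhesion molecule, by 0.63, and Nfkbie, an inhibitor of NF-kappaB, by 0.61. The list was shifted down (camera adjusted p = 4.33e-06), with an adjusted p = 0.0675 with an estimated correlation. Of 23 immediate early genes, which respond first to stimulation, 8 fell and 0 rose (9 and 0 adjusted over the list alone; median -0.34). Zfp36, which destabilises cytokine mRNAs, fell by 0.87, Klf4 by 0.81, Ier5 by 0.74 and the AP-1 component Junb by 0.61 (camera adjusted p = 4.70e-05, and adjusted p = 0.605 with an estimated correlation). Of 14 Th1 genes, 4 fell and 0 rose (5 and 0 adjusted over the list alone; median -0.50), among them Tbx21, the lineage factor of Th1 cells, by 1.14, Il12rb1, a chain of the IL-12 receptor, by 0.70, and the chemokine Ccl5 by 0.58 (camera adjusted p = 0.00249, and adjusted p = 0.605 with an estimated correlation). The 18 genes of IL-2 and STAT5 signalling had a median of -0.29, with 0 passing and 9 lower adjusted over the list alone. Il10ra was -0.50 (adjusted p = 0.0727) and Jak1 was -0.47 (adjusted p = 0.0828). That list was shifted down at a camera adjusted p of 0.0150, with an adjusted p = 0.605 with an estimated correlation.

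Of the 23 genes of the type I interferon response, 5 rose in CBP-deleted cells and 0 fell (8 and 0 adjusted over the list alone; median 0.30): Oasl2 by 1.27, Oas2 by 1.03, Ifit3 by 0.86 and Ifit1 by 0.80 were the largest. The camera adjusted p was 1.18e-06, and adjusted p = 0.605 with an estimated correlation. Of 47 oxidative phosphorylation genes, 38 had a positive sign and 1, Uqcrc2 of respiratory complex III, rose (0.39; 1 also adjusted over the list alone), with a median of 0.15 (camera adjusted p = 4.20e-05, and adjusted p = 0.668 with an estimated correlation). Of 39 cell cycle genes 36 were positive and 1, the S phase regulator E2f1, rose (0.52; 1 also adjusted over the list alone). Their median was 0.26 (camera adjusted p = 4.70e-05, and adjusted p = 0.732 with an estimated correlation).

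Among markers of other cell types, 4 of 12 B cell genes fell in CBP-deleted cells and 0 rose (6 and 0 adjusted over the list alone; median -0.30). They were Cd79a by 1.03, Cd79b by 0.84, Cd22 by 0.62 and Ighm by 0.25, all parts or partners of the B cell receptor. The camera adjusted p was 0.00176, and adjusted p = 0.605 with an estimated correlation. The list also lost its call with fry (0.0826) and with every probe set on its own (0.179, range over 23 alternatives 0.000377 to 0.605). Ighm had 11 probe sets, of which 2 shared this sign, and their mean rose by 1.01 (adjusted p = 0.0477, in a range of 0.0199 to 0.154 over 21 alternatives). The 16 myeloid and neutrophil markers had a median of 0.55 with 0 passing (0 also adjusted over the list alone), and a camera adjusted p of 0.0287, with an adjusted p = 0.732 with an estimated correlation. S100a8, an abundant neutrophil protein, was 2.47 higher (SE 0.87, adjusted p = 0.129), and S100a9 2.48 higher (adjusted p = 0.133). S100a8 read 11.01 in CBP-deleted replicate 3 and 7.64 in each of replicates 1 and 2, against 6.98, 4.92 and 6.99 in the controls. The 5 plasma cell markers had a median of -0.07, with 0 passing and Tnfrsf17 alone higher adjusted over the list alone (camera adjusted p = 0.995). Of 13 CD8 T cell and NK cell markers, Gzmk, a granzyme, rose by 1.02 and Cd8b1 by 0.74 (2 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.135, and 0.0443 without CBP-deleted replicate 1 in a range of 0.0443 to 0.607 over 23 alternatives).

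This comparison is limited by single arrays and, for lists, by the correlation of their genes. In it 0 of the 611 calls changed sign without any single array. The arrays of the 2 groups did not overlap for these genes, so no sign could change and this does not show stability. Fewer arrays make the test less sensitive. The count fell to 85, 123 and 91 genes without CBP-deleted replicate 3, 1 or 2, and to 130 without control replicate 1 and 393 without p300-deleted replicate 2. It rose to 1131 without control replicate 3. Of 75 named genes that passed, 52 lost their call without at least 1 array. The losses were 49, 47 and 41 without CBP-deleted replicate 3, 2 or 1, and 43 without control replicate 1. Penk, Ecm1, Traf1 and Zfp36 kept their calls. The cell cycle call was lost without control replicate 2 (adjusted p = 0.276, range over 23 alternatives 4.44e-16 to 0.732), oxidative phosphorylation without control replicate 3 (0.0511, range 9.59e-11 to 0.668) and IL-2 and STAT5 signalling without control replicate 1 (0.0652, range 0.00436 to 0.605), and the myeloid call without CBP-deleted replicate 3 (0.637), control replicate 1 (0.0652) or control replicate 2 (0.247; range 0.000508 to 0.732). None of the 9 shifted lists kept its call with an estimated correlation, which gave each list its highest adjusted p over 23 alternatives.

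p300-deleted and control cells were compared in the same way. Slpi, a leukocyte protease inhibitor, rose 6.99-fold from log2 6.94 ± 0.45 to 9.75 ± 0.67 (SD, n = 3), and Mcpt8, a protease of basophils, rose 5.42-fold (log2 2.44, SE 0.42). Of immunoglobulin transcripts, Igha, the heavy chain of IgA, rose from 11.72 ± 0.41 to 13.80 ± 0.09, near the top of the scale (at least 4.25-fold, adjusted p = 0.000480), and Igk, of the kappa light chain, from 8.10 ± 0.47 to 10.27 ± 0.45 (4.49-fold). Aurkb, a mitotic kinase, fell 2.58-fold (log2 -1.37, SE 0.24). Tmprss13, a membrane serine protease, fell from 5.36 ± 0.31 to 3.14 ± 0.14 (adjusted p = 9.13e-05), below the level of Xist, so its log2 fold change of -2.22 is a lower bound. In all, 503 of 12393 genes changed, 250 higher and 253 lower; 130 of those higher and 124 of those lower changed at least 1.5-fold. With each array's median subtracted the split was 194 higher and 300 lower. In each of the 503 the arrays of the 2 groups did not overlap, and 20.3% of all genes separated in this way, where chance gives 10%.

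Other leading genes that rose in p300-deleted cells were Klrb1b (2.32, against the same controls), the kappa light chain transcript Igk-V21 (2.04), Camp, the antimicrobial cathelicidin of neutrophils (2.13), and Tnfrsf17, the receptor BCMA of plasma cells (1.79), as log2 fold changes. Fcer1a, the alpha chain of the IgE receptor (1.66), Cma1, a mast cell chymase (1.65), and Ctsg, a neutrophil granule protease (1.64), also rose. Falls were seen for Emp1, an epithelial membrane protein (-1.63), Apobec3, a cytidine deaminase that acts against retroviruses (-1.34), Ankrd33b (-1.33), Csrp2 (-1.31) and the sulfotransferase Chst2 (-1.30). Nek2 (-1.26), Cep55 (-1.25) and Kif2c (-1.23), which act in cell division, and Cbx7, a Polycomb protein (-1.20), fell as well. Kif2c was -0.67 with probe sets ending in _x_at left out (adjusted p = 0.104, range over 21 alternatives 0.00448 to 0.104) and Cep55 -0.68 with the mean of its 2 probe sets (0.0697, range 0.0144 to 0.142), and neither passed there. The changes of Igk-V21 and Cbx7 are lower bounds, since their lower groups read 3.49 and 3.73. Ankrd33b read 3.04 in p300-deleted cells and 3.89 and 3.84, near the level of Xist, in control replicates 1 and 2. Control replicate 3 read 5.38, so the size of the Ankrd33b fall depends on that array.

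Of 39 cell cycle genes, 20 fell in p300-deleted cells and 0 rose (35 and 0 adjusted over the list alone), with a median of -0.86. Beside Aurkb, the largest falls were in Rrm2, a subunit of ribonucleotide reductase (-1.17), the mitotic kinase Aurka (-1.14) and the checkpoint kinase Bub1 (-1.10). The camera adjusted p was 5.95e-23, and adjusted p = 0.545 with an estimated correlation. The mean of the list relative to the control mean was -0.57, -0.97 and -0.89 in the p300-deleted arrays and -0.12, -0.38 and 0.50 in the controls. The 18S reading was highest in the same p300-deleted group (8.52) and within it highest in replicate 2 (9.62), the array lowest in cell cycle transcripts. Control replicate 3 went the other way, second highest in 18S (8.88) and highest in cell cycle transcripts (0.50). The list kept its call with the 18S level as a covariate, with which 192 of the 503 changed genes kept theirs. A link to 18S is therefore not settled. Genes of hypoxia response and glycolysis fell in 5 of 25 cases and rose in 0 (6 and 0 adjusted over the list alone; median -0.20). Adm, adrenomedullin, fell by 0.95, and the glycolytic genes Tpi1 and Pkm by 0.50 and 0.37 (camera adjusted p = 0.000203, and adjusted p = 0.161 with an estimated correlation). Of 15 cholesterol synthesis genes, Idi1 fell by 0.49 and Hmgcs1 by 0.43 (1 higher and 6 lower adjusted over the list alone; median -0.24; camera adjusted p = 0.00837, and adjusted p = 0.545 with an estimated correlation). Of the 4 probe sets of Hmgcs1, 3 had this sign. In CBP-deleted cells 1 cholesterol gene rose and 2 fell (2 and 6 adjusted over the list alone), among them Hmgcs1 by 0.45, and the list did not pass (camera adjusted p = 0.0705, and 0.0399 without CBP-deleted replicate 3 in a range of 0.00528 to 0.605 over 23 alternatives).

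All 5 measured plasma cell markers rose in p300-deleted cells (5 also adjusted over the list alone), with a median of 1.20. They were Tnfrsf17 (1.79), Derl3, a factor of endoplasmic reticulum quality control (1.26), Prg2 (1.20), Jchain, the joining chain of secreted IgA and IgM (1.03), and Sdc1, the plasma cell surface marker CD138 (0.80, adjusted p = 0.0474). The camera adjusted p was 5.49e-08, and adjusted p = 0.247 with an estimated correlation. Of 12 B cell markers, Ighm alone rose (by at least 0.33; 1 also adjusted over the list alone), the median was -0.14 and the list did not pass (camera adjusted p = 0.850). The Ighm probe set used reads 13.99 to 14.06 in the p300-deleted arrays, at the top of the scale (array maxima 14.05 to 14.08), so its differences from them are bounds. The result depends on the probe sets: the mean of the 11 probe sets of Ighm rose by 2.03 (adjusted p = 0.00419, range over 21 alternatives 0.00419 to 0.0687). With every probe set on its own the list shifted up (camera adjusted p = 0.00226, range over 23 alternatives 0.00226 to 0.963). Of 16 myeloid and neutrophil markers 15 were positive and Camp alone rose (3 adjusted over the list alone; median 0.92; camera adjusted p = 0.000389, and adjusted p = 0.569 with an estimated correlation). Of 13 CD8 T cell and NK cell markers 11 were positive and Ncr1, an NK cell receptor, rose by 1.43 (7 adjusted over the list alone; median 0.36; camera adjusted p = 0.000203, and adjusted p = 0.247 with an estimated correlation).

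**Figure D2:**
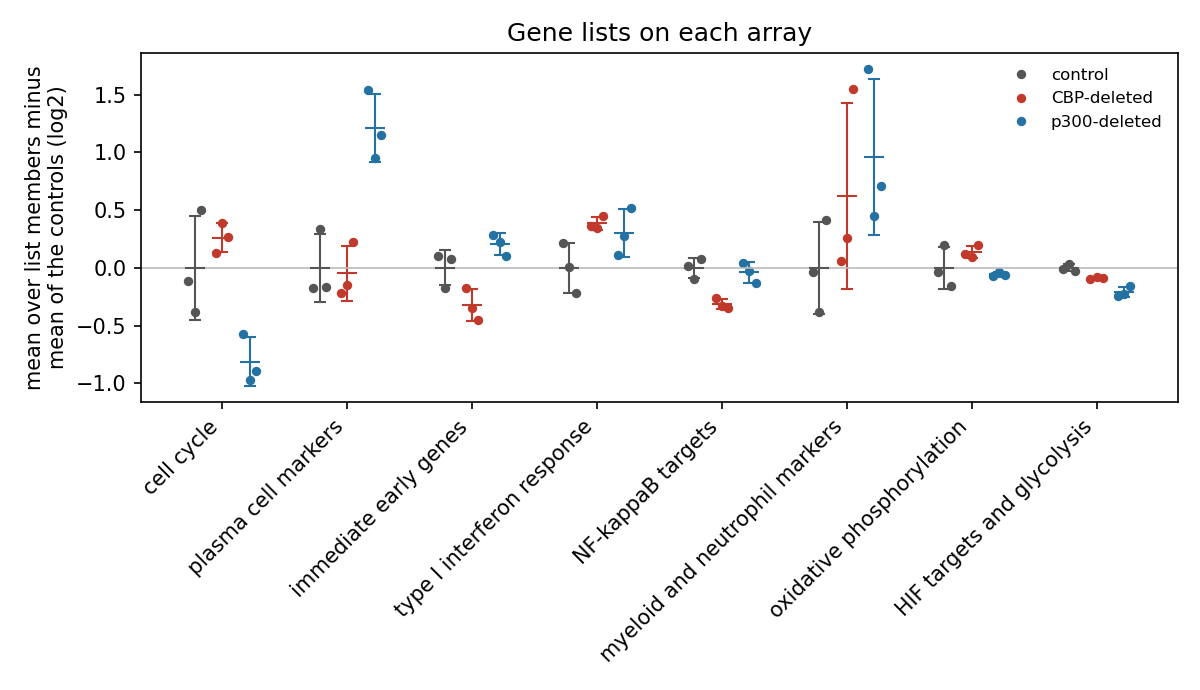
Mean log2 expression over the members of 8 gene lists in each array, relative to the mean of the controls (vertical axis), by group on the horizontal axis; points are arrays, bars the group means and error bars the SD (n = 3). Cell cycle scores of p300-deleted arrays lie between -0.97 and -0.57 and their plasma cell scores between 0.96 and 1.54, outside the range of the controls.

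Of 23 type I interferon genes, Oasl2 rose in p300-deleted cells by 1.09 and Ifit3 by 0.90 (5 higher and 0 lower adjusted over the list alone; median 0.24; camera adjusted p = 1.84e-05, and adjusted p = 0.569 with an estimated correlation). Among 23 immediate early genes the antiproliferative gene Btg2 rose by 1.34 and the AP-1 component Jun by 0.99 (2 also adjusted over the list alone; median 0.16; camera adjusted p = 0.0183, and adjusted p = 0.569 with an estimated correlation). Of 19 genes of T cell receptor signalling, Cd4 rose by 0.66 and Cd3g by 0.28 (2 also adjusted over the list alone; median 0.09; camera adjusted p = 0.0395, and adjusted p = 0.569 with an estimated correlation). In CBP-deleted cells 0 of these 19 changed (0 adjusted over the list alone; camera adjusted p = 0.995). NF-kappaB targets did not shift in p300-deleted cells, with Ccl5 and Relb lower by 0.57 and 0.39 (3 lower adjusted over the list alone; camera adjusted p = 0.322). Of 18 IL-2 and STAT5 genes, the cytokine gene Lta rose by 0.60 (4 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.577). Th1 genes did not shift, with Ccl5 alone lower (1 also adjusted over the list alone; camera adjusted p = 0.247, and 0.00324 without p300-deleted replicate 1 in a range of 0.00270 to 0.824 over 23 alternatives), nor did oxidative phosphorylation, with 0 of 47 changed (0 adjusted over the list alone; camera adjusted p = 0.322, and 0.0132 without control replicate 3 in a range of 0.0132 to 0.934).

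In the p300 comparison 0 of the 503 calls changed sign without any single array. Here too the arrays of the 2 groups did not overlap for these genes, so no sign could change. Fewer arrays make the test less sensitive. This comparison also varied with single arrays, those of the CBP-deleted group included. Its count fell to 65, 231, 300, 264 and 208 genes without p300-deleted replicate 2, p300-deleted replicate 1, CBP-deleted replicate 1, CBP-deleted replicate 2 or control replicate 1 and rose to 854 without control replicate 3; 43 of 59 named genes that passed lost their call without at least 1 array, most of them (41) without p300-deleted replicate 2, but not Slpi, Igha, Igk, Tnfrsf17, Jchain, Derl3, Tmprss13 or Rgs1. The immediate early call was lost without p300-deleted replicate 1 (adjusted p = 0.0815) or control replicate 2 (0.248; range over 23 alternatives 0.00222 to 0.569), and the T cell receptor call without p300-deleted replicate 2 (0.0648), p300-deleted replicate 3 (0.0760), control replicate 2 (0.172) or control replicate 3 (0.212; range 0.00100 to 0.569). No list of the 9 kept its call with an estimated correlation.

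The knockouts were compared directly to test whether their effects differ. Apobec3 was 5.61-fold higher in CBP-deleted than in p300-deleted cells, at log2 9.32 ± 0.08 against 6.83 ± 0.14 (SD, n = 3; log2 fold change 2.49, SE 0.26), with the controls between them at 8.17 ± 0.73. Cbx7 was higher by at least 2.15 on the log2 scale (SE 0.29), with p300-deleted cells at 3.73, the level of Xist. Bub1 (3.26-fold), Birc5, also called survivin (3.19-fold), and the spindle kinase Ttk (3.11-fold) were higher in CBP-deleted cells. Igk was lower in CBP-deleted cells, at 8.26 ± 0.27 against 10.27 ± 0.45 (4.03-fold). In all, 645 genes differed, 396 higher in CBP-deleted cells and 249 higher in p300-deleted cells; 226 and 125 of them differed at least 1.5-fold. In each of the 645 the arrays did not overlap, and 30.1% of all genes separated in this way, where chance gives 10%.

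Further genes higher in CBP-deleted than in p300-deleted cells were Shcbp1 (1.56), Ccna2 and Ccnb2, which encode cyclins A2 and B2 (1.55 and 1.53), the spindle factor Spag5 (1.55), and Cep55 (1.55), as log2 differences. The centromere protein gene Cenpk and Ube2c, which drives mitotic exit, were each 2.83-fold higher. Lower in CBP-deleted cells were the light chain transcripts Igkv6-14 (-2.05), Igkv4-68 (-1.90), Igkv4-72 (-1.79) and Iglv1 (-1.47), and Slpi (-1.81), Prg2 (-1.73) and Derl3 (-1.25). Fosb, an AP-1 component (-1.38), Oosp1 (-1.38) and Sh3gl3 (-1.30) were lower as well. Of the 4 probe sets of Igk, 3 had this sign.

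Of 39 cell cycle genes 36 were higher in CBP-deleted cells and 0 lower (37 and 0 adjusted over the list alone), with a median difference of 1.15 (camera adjusted p = 5.30e-37, and adjusted p = 0.192 with an estimated correlation). All 5 plasma cell markers were lower (5 also adjusted over the list alone; median -1.12), among them Tnfrsf17 (-1.12) and Jchain (-1.10); the camera adjusted p was 1.10e-07, and adjusted p = 0.192 with an estimated correlation. Immediate early genes differed in 12 of 23 cases, all lower in CBP-deleted cells (16 adjusted over the list alone; median -0.51), led by Fosb, Klf4 (-1.11), Jun (-0.92) and Zfp36 (-0.90). The camera adjusted p was 1.41e-10, and adjusted p = 0.192 with an estimated correlation. NF-kappaB targets were lower in 4 of 16 cases (4 adjusted over the list alone; median -0.21), with Traf1 at -0.80, Tnf at -0.70, Bcl3 at -0.43 and Nfkbia at -0.29 (camera adjusted p = 0.000179, and adjusted p = 0.182 with an estimated correlation). Of 18 IL-2 and STAT5 genes 4 were lower (4 adjusted over the list alone; median -0.14): Lta (-0.90), the STAT targets Socs2 (-0.74) and Cish (-0.71), and Socs3 (-0.55), at a camera adjusted p of 0.00313, and adjusted p = 0.359 with an estimated correlation. CREB targets were lower in 2 of 14 cases (2 adjusted over the list alone; median -0.18), the phosphatase gene Dusp1 (-0.78) and Fos (-0.67), at a camera adjusted p of 0.0117, and adjusted p = 0.359 with an estimated correlation. Against the control, CREB targets did not shift: 1 rose and 3 fell in CBP-deleted cells (1 and 5 adjusted over the list alone; camera adjusted p = 0.180) and 1, the clock gene Per2, fell by at least 0.48 in p300-deleted cells, to 3.74, the level of Xist (1 adjusted over the list alone; camera adjusted p = 0.247).

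Treg signature genes were lower in CBP-deleted than in p300-deleted cells in 8 of 30 cases and higher in 1 (13 and 3 adjusted over the list alone; median -0.19). Ecm1 differed by -1.19, Gpr83 by -0.87 and Izumo1r by -0.78, and Plagl1 by 1.00 in the other direction, a difference of 0.30 with probe sets ending in _x_at left out (adjusted p = 0.580, range over 21 alternatives 0.000829 to 0.580). The list was shifted (camera adjusted p = 0.00907, and adjusted p = 0.192 with an estimated correlation). Genes of hypoxia response and glycolysis were higher in 7 of 25 cases and lower in 1 (8 and 1 adjusted over the list alone; median 0.07), with Tpi1 at 0.85, hexokinase Hk2 at 0.67, the oxygen sensor Egln3 at 0.65 and the glucose transporter Slc2a3 at -0.74. The camera adjusted p was 0.0381, and adjusted p = 0.192 with an estimated correlation. In CBP-deleted cells against the control, 2 members of this list rose and 3 fell (6 and 6 adjusted over the list alone; camera adjusted p = 0.560), among them Slc2a3, which fell by 0.98. With the mean of its 4 probe sets Slc2a3 was -0.50 against the control (adjusted p = 0.0192, range over 21 alternatives 2.76e-05 to 0.0192) and -0.40 between the knockouts (0.0349, range 0.000104 to 0.0349). Oxidative phosphorylation genes were positive in 43 of 47 cases with 1, the cytochrome c gene Cycs, past the threshold at 0.46 (3 adjusted over the list alone; median 0.20; camera adjusted p = 2.50e-08, and adjusted p = 0.482 with an estimated correlation). B cell markers had Ighm alone lower, by at least 0.58 since it reads at the top of the scale in p300-deleted arrays (5 lower adjusted over the list alone; median -0.41; camera adjusted p = 0.00313, and adjusted p = 0.428 with an estimated correlation). The thymocyte marker Dntt, which adds nucleotides at antigen receptor joints, was the 1 of 8 that was lower, at -0.75 (3 adjusted over the list alone; median -0.26; camera adjusted p = 0.0157, and adjusted p = 0.192 with an estimated correlation). Against the control, thymocyte markers did not shift, with Dntt lower by 0.58 in CBP-deleted cells, or by 0.13 and not passing with probe sets ending in _x_at left out (1 adjusted over the list alone; camera adjusted p = 0.262) and Cd1d1 higher by 0.38 in p300-deleted cells (1 adjusted over the list alone; camera adjusted p = 0.265). In T cell receptor signalling the phosphatase gene Ptpn6 was lower at -0.36 (1 higher and 3 lower adjusted over the list alone; median -0.14; camera adjusted p = 0.0447, and adjusted p = 0.542 with an estimated correlation).

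Lists that passed against the control and did not pass between the knockouts included the type I interferon response (0 of 23, and 0 adjusted over the list alone; camera adjusted p = 0.324), myeloid and neutrophil markers (0 of 16, and 0 adjusted over the list alone; 0.304), Th1 genes with Tnf lower (3 lower adjusted over the list alone; 0.0889), cholesterol synthesis (0 of 15, and 0 adjusted over the list alone; 0.573) and CD8 T cell and NK cell markers (0 of 13, with 1 higher and 3 lower adjusted over the list alone; 0.0889). Some of these passed between the knockouts without 1 array: interferon (0.0145, range over 23 alternatives 0.0145 to 0.942) without p300-deleted replicate 3, and Th1 genes without p300-deleted replicate 2 (0.0478) or 3 (0.00639, range 0.00639 to 0.610). CD8 T cell and NK cell markers passed without CBP-deleted replicate 3 (0.0226) or p300-deleted replicate 3 (0.0139, range 0.0139 to 0.497), and myeloid and neutrophil markers without CBP-deleted replicate 3 (0.000140) or p300-deleted replicate 2 (0.0341; range 0.000140 to 0.978).

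The count of genes that differed between the knockouts changed with single arrays: it was 372, 212 and 298 without CBP-deleted replicate 1, 2 or 3, 336, 287 and 426 without p300-deleted replicate 1, 2 or 3, and 1041 and 987 without control replicate 2 or 3; 23 of 66 named genes that passed lost their call without at least 1 array, with up to 23 lost without CBP-deleted replicate 2, and Apobec3, Cbx7, Bub1, Birc5, Tpi1 and Tnfrsf17 kept theirs. The CREB call was lost without CBP-deleted replicate 3 (adjusted p = 0.0519, range over 23 alternatives 0.00164 to 0.359), the hypoxia and glycolysis call without CBP-deleted replicate 1 (0.0536) or p300-deleted replicate 1 (0.116; range 0.0104 to 0.192), and the T cell receptor call without CBP-deleted replicate 2 (0.0902), CBP-deleted replicate 3 (0.109), p300-deleted replicate 2 (0.0837) or p300-deleted replicate 3 (0.0531; range 0.0101 to 0.542). None of the 12 lists kept its call with an estimated correlation.

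Of the 35 lists tested, 18 were shifted in none of the comparisons (lowest adjusted p = 0.0555), though single members changed. Some passed in alternatives. With every probe set on its own, naive and quiescent T cell genes passed in CBP-deleted cells (camera adjusted p = 0.00729) and between the knockouts (0.0134). In p300-deleted cells pan T cell markers (0.0350) and heat shock genes (0.0408) passed that way, and platelet markers with the 18S covariate (0.00401). Without CBP-deleted replicate 3 and p300-deleted replicate 1 together Th17 genes passed between the knockouts (0.0186). Effector Treg and activation genes had 3 higher and 2 lower of 20 in CBP-deleted cells (3 and 3 adjusted over the list alone) and 1 higher and 2 lower in p300-deleted cells (1 and 8 adjusted over the list alone), with 0 different between the knockouts (0 adjusted over the list alone). That last comparison gave the 0.0555 and passed, higher in CBP-deleted cells, in 13 of 23 alternatives (0.00564 to 0.530), among them those without CBP-deleted replicate 2 (0.0454) or 3 (0.0494), p300-deleted replicate 1 (0.00727) and control replicate 2 (0.0408) or 3 (0.0284). Cd44, an adhesion receptor of activated cells, passed as lower in both knockouts, by 0.73 and 0.70, but lost both calls in most of 21 alternatives (adjusted p from 0.0208 to 0.144 and from 0.0338 to 0.194). With the mean of its probe sets it was -0.44 and -0.53, and neither passed. Of 14 naive and quiescent T cell genes, Igfbp4 rose and Id3, an inhibitor of E proteins, fell by 1.19 in CBP-deleted cells (3 and 1 adjusted over the list alone), and 0 changed in p300-deleted cells (4 and 3 adjusted over the list alone). Both genes also differed between the knockouts (2 and 1 adjusted over the list alone). Il21 rose in both knockouts, as 1 of 9 Tfh genes (3 in CBP-deleted and 1 in p300-deleted cells adjusted over the list alone), while Cxcr5, the receptor that leads cells into follicles, fell by 0.95 in CBP-deleted cells (1 adjusted over the list alone) and was lower there than in p300-deleted cells by -0.91 (1 higher and 1 lower adjusted over the list alone). As Th17 genes, Il21 and Ahr rose in CBP-deleted cells (2 higher and 2 lower of 7 adjusted over the list alone) and Il21 in p300-deleted cells (2 and 1 adjusted over the list alone), and Ahr differed between the knockouts by 1.01 (1 adjusted over the list alone). Of 9 Th2 genes 0 changed in any comparison; adjusted over the list alone the counts were 0 in CBP-deleted cells, 1 higher and 1 lower in p300-deleted cells and 2 higher and 1 lower between the knockouts.

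Chemokine receptor and homing genes had 1 higher (Ccr8) and 2 lower (Cxcr5 and the selectin ligand Selplg) of 20 in CBP-deleted cells (3 and 4 adjusted over the list alone), 0 in p300-deleted cells (0 adjusted over the list alone) and 1 lower between the knockouts (1 adjusted over the list alone). In TGF-beta and Smad signalling Tgfb1 fell by 0.44 in CBP-deleted cells (1 higher and 1 lower of 18 adjusted over the list alone), 0 changed in p300-deleted cells (0 adjusted over the list alone) and Skil and Itgav were lower between the knockouts, at -0.53 and -0.36 (2 adjusted over the list alone). The p53 target Sesn1 fell in both knockouts, by 0.70 and 0.58, and Btg2 and the death receptor gene Fas (0.58) rose in p300-deleted cells; adjusted over the list alone, 2 of 19 were lower in CBP-deleted cells, 2 higher and 1 lower in p300-deleted cells, and 0 between the knockouts. Of 23 apoptosis and survival genes 0 changed in CBP-deleted cells (1 higher and 1 lower adjusted over the list alone), Fas rose in p300-deleted cells (2 and 1 adjusted over the list alone), and Bcl2l11, also called Bim, and Cycs were higher in CBP-deleted than in p300-deleted cells, at 0.58 and 0.46 (3 and 3 adjusted over the list alone). Heat shock and stress genes included Xbp1, a factor of secretory cells, which rose by 0.73 in p300-deleted cells, where Hsp90aa1 fell by 0.37 (2 higher and 1 lower of 18 adjusted over the list alone). In CBP-deleted cells Hspe1 rose by 0.46 and Hspb1 fell by 0.58 (1 and 2 adjusted over the list alone), and 2 members were higher and 2 lower between the knockouts (3 and 3 adjusted over the list alone). Of 11 acetyltransferases and 13 histone deacetylases and sirtuins 0 changed against the control (0 adjusted over the list alone), and Hat1, an acetyltransferase of new histones, was 0.55 higher in CBP-deleted than in p300-deleted cells (1 higher and 3 lower acetyltransferases and 0 deacetylases adjusted over the list alone). Of 34 ribosomal protein genes 0 changed in any comparison (0 adjusted over the list alone), but most read near the top of the scale, where changes are hard to see.

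Pan T cell markers had Cd2 higher by 0.40 and Thy1, Cd6 and Cd5 lower by 0.58, 0.38 and 0.32 in CBP-deleted cells (1 and 3 of 11 adjusted over the list alone), and Cd4, Cd2 and Cd3g higher in p300-deleted cells, at 0.66, 0.48 and 0.28 (3 adjusted over the list alone). Between the knockouts Cd5 and Thy1 were lower in CBP-deleted cells (1 higher and 6 lower adjusted over the list alone). Erythroid markers had Alas2 and Hbb-b2 lower in CBP-deleted cells, by 1.10 and 0.73 (1 higher and 3 lower of 9 adjusted over the list alone), 0 changed in p300-deleted cells (0 adjusted over the list alone) and Tfrc higher by 0.37 between the knockouts (1 adjusted over the list alone). Alas2 read 4.98, 4.79 and 6.04 in control replicates 1, 2 and 3, so the size of its fall depends on control replicate 3. Of 10 dendritic cell and antigen presentation markers, 7 platelet markers and 10 stromal and endothelial markers 0 changed in any comparison. Adjusted over the list alone, 1 platelet marker was lower in CBP-deleted cells, 1 stromal marker was lower in p300-deleted cells and 1 dendritic cell marker was lower between the knockouts. In CBP-deleted cells the stromal list passed without CBP-deleted replicate 3 (0.0286, range over 22 alternatives 0.0255 to 0.605) and the platelet list without control replicate 1 (0.0416, range 0.0133 to 0.838). Between the knockouts the dendritic cell list passed without CBP-deleted replicate 3 (0.0410, range over 23 alternatives 0.0410 to 0.901). Median, mean and test differed in sign for 6 lists in CBP-deleted and 6 in p300-deleted cells against the control, and for 2 between the knockouts. None of these 14 had shifted: their medians lay between -0.10 and 0.18.

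Genes changed in both knockouts were counted to see how far the profiles coincide. Sostdc1, Penk, Klrb1b, Stfa3 and Cpq rose in both, the last by 1.49 in CBP-deleted and 1.51 in p300-deleted cells. Il10, Il21, Oasl2 and Ifit3 also rose in both, and Cnr2, Plxnd1, Klra17, Tmprss13 and Ccl5 fell in both. The Foxp3 reading fell in both as well, which a probe set that does not read the Cre-bearing allele could cause. In all, 133 genes changed the same way in both comparisons with the control, 84 higher and 49 lower (56 and 55 with each array's median subtracted). Another 4 changed in opposite directions: Apobec3 (1.14 in CBP-deleted, -1.34 in p300-deleted cells), Cenpv (0.61 and -0.44), Ighm (-0.25 and 0.33) and the glycolytic gene Tpi1 (0.35 and -0.50). Ighm is not secure among them, since it reads at the top of the scale in p300-deleted arrays and its sign depends on the probe set: the mean of its 11 probe sets rose by 1.01 in CBP-deleted cells (adjusted p = 0.0477, range over 21 alternatives 0.0199 to 0.154). Apobec3 read 8.71, 7.34 and 8.48 in control replicates 1, 2 and 3, so the size of both its changes depends on control replicate 2. Both comparisons use the same 3 controls, so unchanged groups that share their controls were simulated: they gave a mean of 0.01 shared genes and at most 1 in 100 simulations. Unchanged groups call almost no genes, so this does not test the overlap of knockouts that each have changes of their own. Lists of these sizes drawn independently would share 12.4. The controls are too few to give each knockout its own, so part of the excess may come from them. It is also not settled whether the controls carry the Foxp3cre allele. The shared changes therefore cannot be assigned to loss of CBP or p300 alone. Across the 12393 genes, which are not independent replicates, the fold changes correlated at r = 0.519, and rho = 0.463. Simulated unchanged groups gave a mean r of 0.498, up to 0.521, and a mean rho of 0.474, so neither was above what unchanged groups with shared controls gave. The knockouts had changes of their own, which those groups lack. Thus r and rho cannot tell whether the profiles coincide beyond the shared controls. The covariance, 0.0374, was above the simulated 0.00968. The simulation gave all groups 1 pooled spread per gene. The SD of genes about their group means was 0.148, 0.194 and 0.204 in the controls and 0.109 to 0.161 in the knockout arrays. The simulated covariance may therefore be too low a reference for shared controls. Without Foxp3 r was 0.494 and the covariance 0.0338. The shared count was 26, 26 and 26 without CBP-deleted replicate 1, 2 or 3, 69 and 19 without p300-deleted replicate 1 or 2, 24 without control replicate 1 and 352 without control replicate 3.

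**Figure D3:**
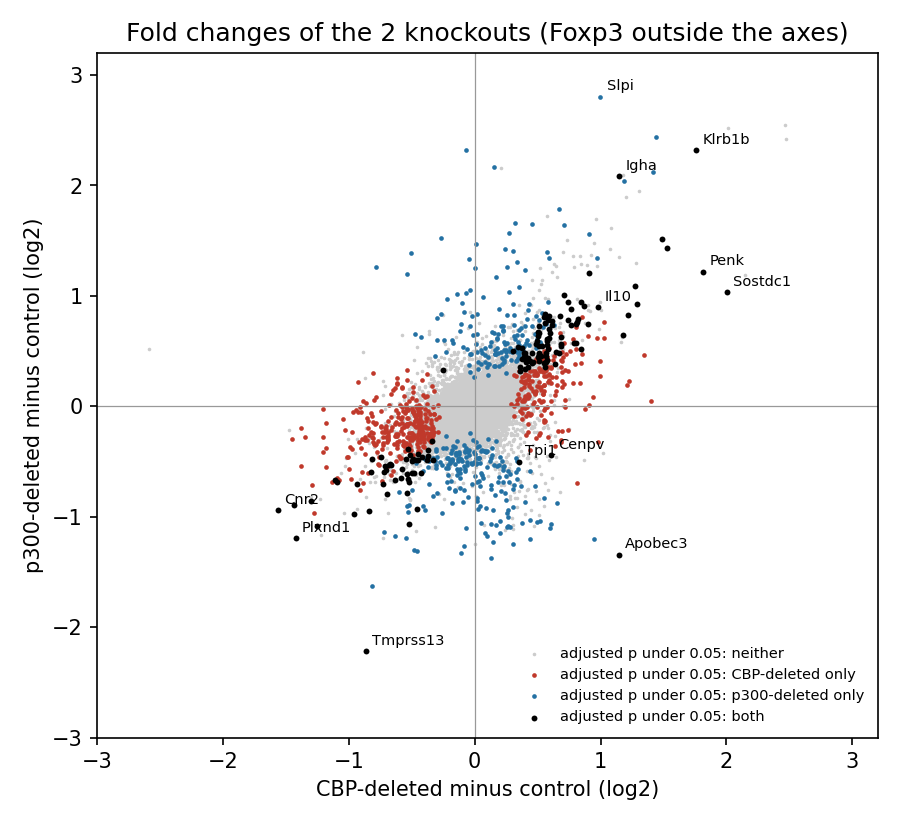
Log2 fold change of each gene in p300-deleted against control cells (vertical axis) over that in CBP-deleted against control cells (horizontal axis), coloured by which comparison passes an adjusted p of 0.05; points are genes, and Foxp3 lies outside the axes. The 133 genes changed the same way lie in the lower left and upper right quadrants and 4, Apobec3 among them, in the other quadrants.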

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

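The tests of causes in this part were chosen after the results were seen, and only the regrouping of arrays was chosen before the data were examined. Results that differ in direction between the knockouts, each past the threshold in all 3 comparisons, were picked out for a closer look, with CBP-deleted minus p300-deleted values tested directly: Apobec3 2.49, Cenpv 1.05, Ighm -0.58 and Tpi1 0.85. The Ighm value is a bound, since its probe set reads at the top of the scale in p300-deleted arrays. Ighm in CBP-deleted cells turns to a rise of 1.01 (adjusted p = 0.0477) with the mean of its probe sets. Picked out too were the cell cycle list (median 1.15) and the immediate early genes (median -0.51), which shifted in opposite directions against the control. With an estimated correlation the cell cycle list had an adjusted p = 0.732 in CBP-deleted and 0.545 in p300-deleted cells, and the immediate early genes 0.605 and 0.569. The rise of the cell cycle list in CBP-deleted cells was lost without control replicate 2 (0.276), and that of the immediate early genes in p300-deleted cells without p300-deleted replicate 1 (0.0815) or control replicate 2 (0.248). The 18S probe sets, which no comparison used, read 9.62 in p300-deleted replicate 2, above the highest control (8.88).

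The Foxp3 reading lay at the bottom of the scale in all 6 knockout arrays. Loss of Treg cells from the sorted fraction could cause this. The other 28 Treg signature genes had a median of -0.21 (SE across genes 0.14) in CBP-deleted and 0.18 (SE 0.12) in p300-deleted cells. That argues against a loss that lowers these genes as a set. Some of them, such as Gzmb and Il10, are also among the effector Treg and activation genes, and all cells were separated by CD25. The medians therefore cannot exclude other CD25+ cells in place of Treg cells. A probe set that does not read the transcript of the Cre-bearing Foxp3 allele could also cause it. The difference of Foxp3 between the knockouts was -0.0772 (SE 0.160). Neither knockout level is told from background, so a small difference comes with any of these causes and does not tell them apart. Controls labelled Foxp3cre that read 9.60 would go against a blind probe set, but they are also called wild type. A blind probe set therefore stays open, as do repression of Foxp3 by either deletion and other CD25+ cells in place of Treg cells.

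Apobec3 and Cbx7, adjacent among measured genes on GRCm38.p6, differed between the knockouts in the same direction, by 2.49 and at least 2.15. Cbx7 fell in p300-deleted cells but did not pass in CBP-deleted cells (0.95, adjusted p = 0.0853). Apobec3 read 9.23 to 9.39 in CBP-deleted and 6.68 to 6.94 in p300-deleted arrays, with controls at 8.71, 7.34 and 8.48. A DNA segment of another strain that changes many genes around the pair could cause this, but 2 changed genes among the 40 nearest were found, the same as the median window of 40 genes, which argues against it. Those 2 were Cbx6 (0.96, adjusted p = 0.0208), in the same direction and next to Apobec3, and Eif3l (0.32, 0.0215). The count cannot exclude a segment of another strain, or an allele, that acts on few genes nearby, so this stays open.

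Plasma cell transcripts were higher in p300-deleted arrays. A lower share of T cells, raising all other cell types alike, could cause this. The plasma cell median exceeded the B cell median by 1.34 (SE across genes 0.23), and by 1.39 (SE 0.22) without Ighm. Genes of these lists correlated (estimates 0.67 and 0.31), so these SE are too small. Medians were positive for myeloid (0.92), CD8 T and NK cell (0.36) and thymocyte markers (0.09). They were negative for dendritic cell (-0.05), erythroid (-0.04), platelet (-0.18) and stromal markers (-0.05). That argues against a rise of all other cell types alike, but not against a gain of several. The B cell list did shift up with every probe set on its own (adjusted p = 0.00226), where Ighm, which plasma cells also transcribe, enters with 11 probe sets and rises by 2.03 in their mean. Plasma cells in the sorted fraction stay open: the median of the 20 measured immunoglobulin genes was 1.32 (SE across genes 0.22). This does not exclude them, and such rises had been seen before this test. The arrays cannot tell whether such cells entered with the separation or whether the sorted cells express these genes.

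Regrouping the 6 arrays of a comparison gives only 10 splits, too few to exclude chance. The real grouping gave 611, 503 and 645 genes, and the highest other split gave 0, 1 and 1, so 1 split of 10 (the real one) was as large in each. For lists the real counts were 9, 9 and 12 and the highest other 11, 12 and 13, with 4, 6 and 3 splits as large. For genes changed in both knockouts, the real count of 133 was 1 of 100 drawn splits of the 9 arrays as large, and the highest other was 2, which argues against a split by chance. Since other splits call almost no genes in either comparison, this does not test whether the knockouts share changes beyond what their common controls give.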

How the results depend on the processing

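The 18S covariate, the removal of 2 arrays together and the correlation without Foxp3 were chosen after the results were seen, and the other settings before the data were examined. Foxp3 kept its call against the control in all 20 alternatives that measured it and drops out when dim probe sets are left out. The correlation of the knockouts lay between 0.453, without dim probe sets, and 0.603, without control replicate 3, against 0.519, within its jackknife SE of 0.105. Counts are given for CBP-deleted against control, p300-deleted against control, between the knockouts and, last, for genes changed in both. At least 1.5-fold left 254, 254 and 351 genes, and an adjusted p of 0.1 gave 1126, 923 and 1035, as construction requires. For the other settings the cause was not tested. Only the arrays of the 2 groups gave 261, 165, 1386 and 35, array weights 1755, 1028, 1467 and 456. The 18S covariate gave 364 and 244 against the control and 47 in both. Without CBP-deleted replicate 3 and p300-deleted replicate 1 together 100, 163, 164 and 19 were called, among them 93, 138 and 157 of the genes called with all arrays. Il10 in CBP-deleted cells (0.96, adjusted p = 0.0568, range 0.000441 to 0.0568) and Jun between the knockouts (-0.84, 0.0545, range 0.000143 to 0.0545) did not pass there. Leaving out each array gave 85 to 1131, 65 to 854, 212 to 1041 and 19 to 352. An estimated correlation left 0 lists in each comparison, and fry called 4 and 2 against the control. Of those 4, NF-kappaB targets and immediate early genes were among the 9 shifted lists, and the Treg signature (0.00880, with Foxp3 among its genes) and stromal markers (0.0255) were not. Crebbp passed between the knockouts with only their arrays (-0.36, adjusted p = 0.0375), array weights (-0.36, 0.0245) and the 18S covariate (-0.43, 0.0312), and against the control in CBP-deleted cells with array weights (-0.36, 0.0328). Leaving out each array moved that difference from -0.42 to -0.26.

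With the replicate number as a replicate block the counts were 364 and 326 against the control and 59 in both. Only 3 of 9 arrays correlated best with their own number, with same-number correlations of -0.23 to 0.27, so the numbers do not pair the arrays.

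Ighm in CBP-deleted cells turned to 1.01 (adjusted p = 0.0477) with the mean of all probe sets, because 2 of its 11 probe sets share the sign of the brightest. B cell markers in p300-deleted cells shifted up with every probe set on its own (adjusted p = 0.00226, range 0.00226 to 0.963), where Ighm enters with 11 probe sets. With the mean of all probe sets, values shrank by over 1.5 times and kept their calls for Klrb1b (to 1.06 in CBP-deleted and 1.39 in p300-deleted cells), Cpq (0.64), Ahr (0.58) and Aqp9 (-0.80) in CBP-deleted cells, Igk in p300-deleted cells (1.34), and Igk (-1.18), Bub1 (1.06), Spag5 (1.00), Cep55 (1.01) and Ahr (0.53) between the knockouts. Cd44 (-0.44), Ier5 (-0.41) and Dntt (-0.29) in CBP-deleted cells, Hsp90aa1 (-0.23) in p300-deleted cells, and Itgav (-0.16) and Tfrc (0.24) between the knockouts did not pass there. Array weights ended the call of Oas2 in CBP-deleted cells (0.61), and the 18S covariate those of Btg2 (0.85), Igk-V21 (1.32) and Sesn1 (-0.38) in p300-deleted cells.

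Among lists, the myeloid markers in CBP-deleted cells lost their call without dim probe sets (adjusted p = 0.536), with array weights (0.0784) and with the 18S covariate (0.0772; range 0.000508 to 0.732), and IL-2 and STAT5 signalling with the mean of probe sets (0.119, range 0.00436 to 0.605). Array weights ended the calls of immediate early genes (0.195, range 0.00222 to 0.569) and T cell receptor signalling (0.447, range 0.00100 to 0.569) in p300-deleted cells. Hypoxia and glycolysis between the knockouts lost its call without dim probe sets (0.151), with every probe set on its own (0.131), with quantile normalization (0.0616) and with the 18S covariate (0.0512; range 0.0104 to 0.192).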

Other observations

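Of 11 genes linked to mast cells and basophils, chosen after values were seen and not a fixed list, 6 rose in p300-deleted cells against the control. The protease genes Mcpt8, Mcpt4, Cma1, Cpa3 and Tpsb2 rose by 2.44, 1.56, 1.65, 1.05 and 1.04 on the log2 scale (adjusted p = 0.0112, 0.0385, 0.0229, 0.0417 and 0.0301), and the IgE receptor chain Fcer1a by 1.66 (0.0399). The stem cell factor receptor Kit was 0.10, the transcription factor Gata2 0.28, the histamine enzyme Hdc 0.09 and the cytokine Il4 -0.29, and these did not pass. Ms4a2, another chain of the IgE receptor, read 2.89 to 3.77 in the 9 arrays, near background, so it cannot show whether that gene rose. In CBP-deleted cells Mcpt8 was 1.44 higher (adjusted p = 0.0782).

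Neutrophil transcripts varied between arrays of a group: S100a8 read 7.64, 7.64 and 11.01 in CBP-deleted, 10.08, 7.69 and 8.77 in p300-deleted and 6.98, 4.92 and 6.99 in control replicates 1 to 3. Of the 10 measured genes nearest to Foxp3, Ccdc22 alone changed in both knockouts, by -0.47 and -0.49 (adjusted p = 0.0364 and 0.0345). Syp, also near Foxp3, was 0.58 higher in CBP-deleted (adjusted p = 0.0628) and rose by 0.94 in p300-deleted cells (0.0103). Of 691 probe sets with several symbols, 23, 30 and 24 changed in the 3 comparisons, and of 1555 not named here 30, 38 and 33.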
